A study of Saccharomyces cerevisiae x Saccharomyces paradoxus and Saccharomyces cerevisiae and Saccharomyces paradoxus with 40 samples.

How the data were processed

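RNA sequencing libraries of S. cerevisiae, S. paradoxus and their hybrid at 4 stages of sporulation were compared, 40 in all. Per the labels' protocols, cells were grown overnight in YPD, a rich medium, then moved to potassium acetate medium, in which starved diploid yeast enters meiosis. Poly-A RNA was isolated, reverse transcribed with poly-A primers, given index adapters and sequenced on a HiSeq, per the labels' protocols. For 3 libraries the labels list 2 indexes. Per the submitters' processing notes reads were aligned with Bowtie 0.12.7, and DESeq 1.8.3 was used. The counting tool, the annotation and the genome builds are not stated, so no coordinates are given, and the R64 annotation of S. cerevisiae served only for names and for which genes are neighbours.

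The authors deposited 4 tables. The first holds raw counts per feature, with the hybrid value equal to the sum of its alleles, and the second holds deposited counts per allele. In all 138520 cells checked the tables were equal to each other in this way, so a hybrid read given to neither allele is in no value. The other two hold variance-stabilised values on a log2-like scale, deposited by the authors and made with DESeq per the submitters' processing notes. The tables list 3463 features. Of these, 246 name no gene (replication origins, repeats, centromeres and telomeres) and were left out of the fits, with 0.392 to 4.95% of the counts of a library. Among 3062 open reading frame names 3058 end in W and 4 in C, so nearly all genes of the other strand, which has 2984 protein-coding genes in the RefSeq annotation, were not analysed here. Of the features 2772 matched that annotation by name.

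Groups were the 3 genotypes at 4 stages, taken from the labels. Counts of 3217 genes were fitted with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr by group) in 1 model of 12 groups, with 3094 genes tested and Benjamini-Hochberg adjustment at 0.05 within each contrast. The common coefficient of variation was 0.871 and the TMM factors ran from 0.531 to 1.34. Contrasts were each stage against T0 within a genotype, S. paradoxus minus S. cerevisiae at each stage and in change from T0, and the hybrid minus each parent and minus their mean at each stage. A gene was outside both parents when it passed against each of them in the same direction. Alleles were compared in the hybrid with the library as a block (2997 genes), and parental against allele differences in a model of allele columns (3092 genes). The latter model had no library block. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and, as an alternative, an estimated one, adjusted over 16 lists. The lists are early meiosis, middle meiosis, spore wall, DNA replication, mitotic G1, haploid and mating, ribosomal proteins, ribosome biogenesis, glycolysis, gluconeogenesis, the TCA cycle, the respiratory chain, stress and reserve carbohydrate, autophagy, proteasome and nitrogen use. Counts per list "adjusted over the list alone" use only the members. List scores, mean log2 CPM of the members in a library, were compared with exact two-sided permutation tests of the difference in means. Fisher's exact test, two-sided, was used for directions. Library matching used the highest Spearman correlation with a parent's stage mean over the 300 genes that changed from T0 to M2 the same way in both parents.

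The groups, contrasts, lists and tests were fixed before the data were examined. Named genes were also chosen by a rule fixed then. In each comparison these are up to 4 members of each list past the threshold with the largest change and a mean count of at least 50, the genes with the largest rise and fall whose groups do not overlap, from the top, and always IME1, IME2, NDT80, SUM1, UME6, SPO11, CLB1, CLB3, SPS4, DIT1, HSP12 and ICL1. Genes at 0 in 1 parent and the genes called at T0 between alleles were named after their values were seen. The labels number the replicates, but libraries with the same number were not more alike, so the replicates were not paired.

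Counts in genes ran from 23453 to 7732384 per library and limit what can be detected. Data were simulated with the depths of these libraries and, for each gene, its mean over all of them. Genes were drawn independently, with no difference between the parents, and the changed ones had a mean count of at least 50. In these data the hybrid at M1 against T0 recovered 27 of 100 genes changed 4-fold and 84 of 100 changed 16-fold. There were 5 false calls. The hybrid minus the parental mean at M1 recovered 31% and 81%, with 4 false calls, and genes outside both parents 9% and 66%, with 0. The allele comparison at M1 recovered 13% and 62%, with 2 false calls. With no change simulated between the species at M1 there were 0 calls. In 20 simulations without any difference no gene was outside both parents at any stage. For a group at 0 in all libraries a floor of 3 counts over the group gives the lower bound of a fold. Intervals for shares are Wilson intervals at 95% and cover counting error only, as do the floors.

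Alternatives tried were DESeq2 1.42.0 (Wald test), limma on the deposited log2 values, DESeq2 size factors, no filter on low counts, only the groups compared, a replicate block and leaving out each library in turn. After the data were seen, fits without the 4 libraries with the lowest median counts, without hybrid T0 replicate 1, without genes low in the hybrid at all stages, of the hybrid change minus the parental change, and of alleles at 1 stage only were added. R 4.3.3, Python 3.11.15, scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9 were used.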

Results

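Messenger RNA was sequenced from sporulating cultures of the budding yeasts S. cerevisiae and S. paradoxus and of the hybrid between them. The question, per the series title, is whether genes of meiosis are expressed at another time in the hybrid than in its parents. Cultures were sampled at 4 stages: entry into sporulation medium (T0, the control), the start of meiosis I (M1), the overlap of meiosis I and II (M1M2) and the end of meiosis II (M2). Each parent had 3 libraries per stage and the hybrid 4, which makes 40 libraries in 12 groups. The hybrid cultures came from both directions of the cross, but the labels do not say which came from which, so the direction was not compared. The deposited tables held 3217 genes, nearly all on 1 strand of the chromosomes. The meiotic regulators IME1, SUM1, UME6 and SPO11 and the genes SPS4 and ICL1 lie outside them and were not analysed here.

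Counts in genes ranged from 23453 to 7732384 per library, with a median of 1348916. The libraries with the fewest counts were S. cerevisiae M1M2 replicate 2 (23453), hybrid M2 replicate 3 (117049), S. cerevisiae M1 replicate 2 (159496) and S. paradoxus M2 replicate 2 (300704). These 4 are called shallow below, and the fits without them were chosen after the data were seen. For the hybrid at M1 against T0, simulated 4-fold changes were found for 27% of genes and 16-fold changes for 84%. The changed genes all had a mean count of at least 50, and small differences could not be detected. Changes are given as log2 values ± SE from edgeR, "rose" and "fell" are used for genes past an adjusted p of 0.05, and n is 3 for each parental group and 4 for each hybrid group. Where a camera result passed with all libraries and no value for an estimated correlation is printed, it passed with that correlation too. Camera results without the shallow libraries used the preset correlation only. For a gene at 0 in every library of a group, a lower bound is given, against 3 counts over the group. A change of scaling from TMM to size factors shifted the median of all genes by 0.115, 0.119 and 0.117 at the 3 later stages of S. paradoxus, by 0.141 and 0.219 at M1 and M2 of the hybrid, by -0.199 between the species at T0 and by 0.19, 0.277 and 0.206 in the differences between the species in change.

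In S. cerevisiae at M1, most genes of ribosome biogenesis fell and 5 of 22 early meiotic genes rose. HOP1 (YIL072W), an axis protein of meiotic chromosomes, rose by 3.76 ± 0.83. IME2 (YJL106W), a kinase that starts meiosis, rose by 3.28 ± 0.71 and DMC1 (YER179W), the meiotic recombinase, by 3.08 ± 0.78. Some glycolytic genes were higher too, with ENO2 (YHR174W, enolase) at 5.41 ± 1 and PGK1 (YCR012W, phosphoglycerate kinase) at 5.02 ± 0.74. MDH1 (YKL085W), of the TCA cycle, rose by 3.5 ± 0.64, and MET3 (YJR010W), of sulfate assimilation, by 5.29 ± 1.1. RLP24 (YLR009W) and DBP2 (YNL112W), which act in assembly of the large ribosomal subunit, had changes of -6.58 ± 1.3 and -5.7 ± 0.94. The peptide transporter gene PTR2 (YKR093W) changed by -6.9 ± 1.2. IRC7 (YFR055W), at 0 in the M1 libraries, was at least 229-fold lower. The transcription factor NDT80 (YHR124W), which starts the middle phase of meiosis, was at 2.01 ± 0.69 (adjusted p = 0.0525). The stress gene HSP12 (YFL014W) was at 0.339 ± 0.69, but at -2.79 and past the threshold without M1 replicate 2. CLB1 (YGR108W) and CLB3 (YDL155W), cyclins of the meiotic divisions, were at -0.154 ± 0.83 and 0.524 ± 0.63, and DIT1 (YDR403W), of the spore wall, at 0.971 ± 1.4, none past the threshold. By list, 24 of 31 ribosome biogenesis genes fell (31 adjusted over the list alone; adjusted p = 3.13e-20, none positive). Of 7 genes each, 4 rose for glycolysis and 4 for the TCA cycle (5 and 7 positive, adjusted p = 0.000476 and 5.01e-05; 4 and 4 adjusted over the list alone). Of the early meiosis genes 17 were positive (5 up adjusted over the list alone; adjusted p = 0.00176, but adjusted p = 0.281 with an estimated correlation and 0.242 without the shallow libraries). Ribosomal protein genes had a median of -1.91 with 5 of 72 called (2 adjusted over the list alone; none positive, adjusted p = 4.44e-12, but adjusted p = 0.0903 with an estimated correlation). In all, 126 genes rose and 148 fell. The total of 274 was 162 without T0 replicate 1, 167 without T0 replicate 3 and 134 without M1 replicate 2. Without the last of these the adjusted p of IME2 was 0.161 and that of DMC1 0.236. The adjusted p of DMC1 was 0.0635 without T0 replicate 3. That of NDT80 was 0.0257 and 0.0496 without M1 replicates 1 and 3, and that of IRC7 was 0.0723 and 0.0647.

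In S. cerevisiae at M1M2, 17 of 22 early meiosis genes rose. HOP1 rose by 8.06 ± 0.99, DMC1 by 7.57 ± 0.95 and HOP2 (YGL033W), which guides homologous pairing, by 7.98 ± 1.5. IME2 was 6.01 ± 0.81 above T0, and NDT80 4.31 ± 0.76. AMA1 (YGR225W), a meiotic activator of protein degradation, rose by 5.35 ± 0.9, and CDA1 (YLR307W), a chitin deacetylase of the spore wall, by 3.39 ± 0.84. RNR1 (YER070W), which makes DNA precursors, rose by 3.73 ± 0.9, and ATG1 (YGL180W), a kinase of autophagy, by 3.6 ± 0.74. RPL21A (YBR191W) changed by -4.71 ± 1.1 and RRP9 (YPR137W), of ribosomal RNA processing, by -6.52 ± 1.4. CLB1 (-0.62 ± 0.97), CLB3 (0.855 ± 0.66), DIT1 (1.25 ± 1.3) and HSP12 (-0.175 ± 0.69) did not pass. For the early meiosis list 22 were positive (18 up adjusted over the list alone; adjusted p = 6.42e-20). Of 22 middle meiosis genes 12 rose (13 adjusted over the list alone; 20 positive, adjusted p = 5.34e-10, but adjusted p = 0.0655 with an estimated correlation). Of 72 ribosomal protein genes 44 fell (63 adjusted over the list alone; 1 positive, adjusted p = 6.92e-22). For DNA replication 4 of 22 rose (4 adjusted over the list alone; 16 positive, adjusted p = 0.12, but 0.00894 without the shallow libraries), so the list did not pass with all libraries. The total of 384 genes (216 up, 168 down) was 248 without T0 replicate 1, 247 without T0 replicate 3 and 225 without M1M2 replicate 3.

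By M2, S. cerevisiae expressed the middle and late sporulation programme. SPO19 (YPL130W), SPS22 (YCL048W) and PES4 (YFR023W), of the middle phase, rose by 8.09 ± 1, 8.01 ± 1 and 7.84 ± 0.96. The spore wall genes CDA1 and GAS4 (YOL132W, a glucan-modifying enzyme) rose by 8.22 ± 0.96 and 7.65 ± 0.91, and DIT1, which makes dityrosine, by 6.9 ± 1.4. NDT80 was up by 6.61 ± 0.82, IME2 by 6.18 ± 0.81, CLB3 by 3.49 ± 0.69 and CLB1 by 2.89 ± 0.88 (adjusted p = 0.0544 without T0 replicate 1). HXT10 (YFL011W), a hexose transporter, rose by 8.64 ± 1.2 and ATG1 by 4.22 ± 0.76. STE4 (YOR212W), a mating G protein subunit, rose by 5.32 ± 1.3. Most respiratory genes fell, with CYC1 (YJR048W, cytochrome c) at -3.55 ± 0.91 and ATP2 (YJR121W, ATP synthase) at -3.02 ± 0.61. RPS27A (YKL156W) changed by -7.72 ± 1.2, NOP7 (YGR103W) by -5.84 ± 1.1 and the glycoprotein gene YGP1 (YNL160W) by -4.45 ± 0.75. HSP12 was at -1.69 ± 0.71 (adjusted p = 0.0763, and 0.0299 without T0 replicate 2). Of 22 middle meiosis genes 21 rose (21 adjusted over the list alone; 21 positive, adjusted p = 3.89e-26), and all 7 spore wall genes rose (7 adjusted over the list alone; adjusted p = 3.48e-10). Of 16 respiratory genes 11 fell and 1 rose (11 and 1 adjusted over the list alone; adjusted p = 8e-06, 1 positive), and 61 of 72 ribosomal protein genes fell (63 adjusted over the list alone; none positive, adjusted p = 5.17e-27). Autophagy and haploid genes each had 5 members up (7 and 8 adjusted over the list alone), and 11 of 12 and 10 of 11 were positive, with adjusted p = 0.00748 and 0.00658, but adjusted p = 0.193 with an estimated correlation for both. With the genes at 0 set to their bound the haploid median was 4.43 in place of 4.44. The stage changed 704 genes (346 up, 358 down).

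In S. paradoxus at M1, 10 of 22 early meiotic genes rose and 9 of 15 stress and reserve carbohydrate genes fell. DMC1 rose by 5.4 ± 0.86, HOP1 by 4.4 ± 0.83 and IME2 by 3.69 ± 0.72. The ammonium transporter MEP2 (YNL142W) rose by 4.76 ± 0.95, the amino acid permease GAP1 (YKR039W) by 3.63 ± 0.83 and the malate synthase MLS1 (YNL117W) by 3.64 ± 0.63. CTT1 (YGR088W, catalase), GPH1 (YPR160W, glycogen phosphorylase) and SSA4 (YER103W, a chaperone) changed by -4.86 ± 0.83, -4.22 ± 0.7 and -4.11 ± 0.88. TDH1 (YJL052W), of glycolysis, changed by -6.67 ± 1.1, ALD6 (YPL061W), an aldehyde dehydrogenase, by -4.24 ± 0.87, NOG1 (YPL093W), of ribosome biogenesis, by -4.31 ± 0.89 and RPL13A (YDL082W) by -5.85 ± 1.2. NDT80 (1.09 ± 0.66), CLB1 (-1.34 ± 0.84), CLB3 (1.2 ± 0.63), DIT1 (-2.66 ± 1.3) and HSP12 (-0.802 ± 0.69) did not pass. Of the early genes 21 were positive (15 up adjusted over the list alone; adjusted p = 1.78e-14), and of the stress genes none (12 down adjusted over the list alone; adjusted p = 5.75e-12). Of 16 nitrogen genes 6 rose (8 adjusted over the list alone; 13 positive, adjusted p = 4.77e-08), and of 11 gluconeogenesis genes 4 rose and 1 fell (6 and 2 adjusted over the list alone; 8 positive, adjusted p = 7.38e-06). No proteasome gene passed edgeR, over all genes or adjusted over the list alone, and 13 of 16 were positive (adjusted p = 0.00112, but adjusted p = 0.207 with an estimated correlation). The total of 104 genes (44 up, 60 down) was 66 without M1 replicate 2.

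S. paradoxus at M1M2 expressed genes of the middle phase. SPO21 (YOL091W), of the spindle pole, rose by 6.9 ± 1, SPR3 (YGR059W), a septin of sporulation, by 6.36 ± 0.92 and MAM1 (YER106W), which orients chromosomes in meiosis I, by 7.19 ± 1.4. NDT80 rose by 5.85 ± 0.79, IME2 by 5.26 ± 0.78, GAS4 by 6.23 ± 0.86 and DMC1 by 6.61 ± 0.91. CTT1 changed by -5.96 ± 0.87 and TSL1 (YML100W), of trehalose synthesis, by -4.88 ± 0.84. The hexose transporter HXT2 (YMR011W) changed by -6.66 ± 0.82, the invertase SUC2 (YIL162W) by -6 ± 1.1, RPS20 (YHL015W) by -4.85 ± 1.1 and QCR8 (YJL166W), of the respiratory chain, by -2.61 ± 0.62. CLB3 rose by 1.94 ± 0.65, but its adjusted p was 0.117, 0.131 and 0.131 without T0 replicates 1, 2 and 3 and 0.353 without M1M2 replicate 3. CLB1 (0.511 ± 0.82), DIT1 (0.16 ± 1.1) and HSP12 (0.175 ± 0.69) did not pass. Of 22 early genes 19 rose (19 adjusted over the list alone; 21 positive, adjusted p = 8.33e-25) and of 22 middle genes 17 (18 adjusted over the list alone; 22 positive, adjusted p = 6.89e-22). Of 16 respiratory genes 11 fell (11 adjusted over the list alone; 1 positive, adjusted p = 6.97e-09), and of 15 stress genes 11 (12 adjusted over the list alone; 1 positive, adjusted p = 3.2e-11). With size factors the share of rises among the calls moved from 45.3% to 52.5%. The total of 289 genes (131 up, 158 down) was 188, 178, 182 and 163 without T0 replicates 2 and 3 and M1M2 replicates 1 and 3.

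At M2, S. paradoxus showed SPR3 up by 8.86 ± 1, SPO21 by 8.25 ± 1.1, GAS4 by 8.41 ± 0.94 and DTR1 (YBR180W), a transporter of dityrosine, by 7.98 ± 1.1. NDT80 rose by 7.26 ± 0.84, IME2 by 5.37 ± 0.78 and CLB3 by 3.9 ± 0.7. DIT1 rose by 3.49 ± 1.2, with an adjusted p of 0.0622, 0.166 and 0.0937 without T0 replicates 1, 2 and 3 and of 0.809 without M2 replicate 3. CLB1 (2.29 ± 0.86) and HSP12 (-0.0684 ± 0.69) did not pass. CTT1 changed by -6.22 ± 0.89, GPH1 by -5.8 ± 0.76 and ATP2 by -2.97 ± 0.61. Of 22 middle genes 20 rose (21 adjusted over the list alone; 22 positive, adjusted p = 2.02e-34), and 6 of 7 spore wall genes (6 adjusted over the list alone; 7 positive, adjusted p = 2.6e-11). Glycolysis had 4 of 7 genes down (6 adjusted over the list alone; none positive, adjusted p = 0.00208). The stage changed 468 genes (213 up, 255 down), and 306 without T0 replicate 3.

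In the hybrid at M1, most called genes fell, many of them genes of the ribosome. RPL2B (YIL018W) and RPL14A (YKL006W), of the large subunit, changed by -6.05 ± 0.97 and -5.83 ± 0.97. DBP2 was at -7.01 ± 0.85, NOP1 (YDL014W), of the nucleolus, at -6.72 ± 0.93 and SSB1 (YDL229W), a chaperone bound to ribosomes, at -7.34 ± 0.97. HOP1 rose by 3.9 ± 0.71, DMC1 by 3.78 ± 0.69, REC114 (YMR133W), which starts recombination, by 3.53 ± 0.87 and IME2 by 2.5 ± 0.59. DAL4 (YIR028W), an allantoin permease, rose by 5.97 ± 1.4 and MET3 by 4.25 ± 0.94. NDT80 (-0.22 ± 0.57), CLB1 (-0.43 ± 0.71), CLB3 (0.495 ± 0.55), DIT1 (-1.18 ± 0.98) and HSP12 (0.396 ± 0.6) did not pass. Of 72 ribosomal protein genes 56 fell (63 adjusted over the list alone; none positive, adjusted p = 1.31e-33), and of 31 ribosome biogenesis genes 28 (30 adjusted over the list alone; none positive, adjusted p = 2.97e-28). Of 22 early genes 10 rose (12 adjusted over the list alone; 22 positive, adjusted p = 9.18e-08, but adjusted p = 0.0666 with an estimated correlation). The total of 386 genes (95 up, 291 down) was 246 without M1 replicate 4.

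The hybrid at M1M2 expressed middle and spore wall genes. SSP1 (YHR184W) and SMK1 (YPR054W), needed to build the spore membrane and wall, rose by 6.45 ± 0.9 and 6.35 ± 0.93, SPO19 by 5.89 ± 0.82, CDA1 by 6.19 ± 0.76 and GAS4 by 5.68 ± 0.72. NDT80 rose by 5.48 ± 0.68, IME2 by 4.76 ± 0.66, CLB3 by 3.01 ± 0.59 and CLB1 by 2.86 ± 0.76. RPL21A was at -6.71 ± 0.98, NOG1 at -5.51 ± 0.82, YGP1 at -4.91 ± 0.66 and ATP2 at -2.83 ± 0.52. DIT1 (-0.387 ± 0.96) and HSP12 (-0.94 ± 0.6) did not pass. Of 22 middle genes 20 rose (20 adjusted over the list alone; 21 positive, adjusted p = 1.5e-21), and of 22 early genes 20 (20 adjusted over the list alone; 22 positive, adjusted p = 2.33e-15). Of 72 ribosomal protein genes 61 fell (70 adjusted over the list alone; none positive, adjusted p = 2.51e-31). For mitotic G1 genes 3 of 9 fell (4 adjusted over the list alone; none positive, adjusted p = 0.0696, but 0.048 without the shallow libraries), so that list did not pass with all libraries. In all 685 genes changed (301 up, 384 down). At M2 the numbers were 803 (371 up, 432 down), and with size factors the share of rises moved from 46.2% to 55.6%. SPS22 rose by 7.13 ± 0.86, SMK1 by 7.08 ± 0.96, CDA1 by 6.75 ± 0.78, DIT1 by 6.72 ± 1.2, NDT80 by 6.02 ± 0.69 and CLB3 by 4.69 ± 0.63 at that stage. IME2 was up by 4.28 ± 0.64 and CLB1 by 2.94 ± 0.76, while HSP12 was at -1.11 ± 0.6 and did not pass. SGA1 (YIL099W), a sporulation glucoamylase, rose by 7.94 ± 0.9 and ATG4 (YNL223W), of autophagy, by 4.76 ± 0.75. RPL21B (YPL079W) was at -6 ± 1 and CYC1 at -4.23 ± 0.83. At M2 all 7 spore wall genes rose (7 adjusted over the list alone; adjusted p = 9.78e-11), and 12 of 16 respiratory genes fell while 1 rose (14 and 1 adjusted over the list alone; 1 positive, adjusted p = 9.54e-07). Without T0 replicate 1 the hybrid totals were 326, 593 and 697 at M1, M1M2 and M2. The allele counts of that library are in question, and so are its gene counts, which are their sum.

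The parents differed at T0, as the cultures entered sporulation medium, in genes of reserve carbohydrate and glycolysis. TSL1, GSY2 (YLR258W, glycogen synthase) and GLC3 (YEL011W, glycogen branching) were higher in S. paradoxus by 4.28 ± 0.82, 3.63 ± 0.76 and 3.59 ± 0.63. PGK1 was higher by 3.78 ± 0.7, ENO1 (YGR254W) by 3.61 ± 0.7, TDH1 by 4.93 ± 1 and ALD6 by 4.54 ± 0.88. MLS1, of the glyoxylate cycle, was lower with -3.77 ± 0.63, and CAT2 (YML042W), a carnitine acetyltransferase, with -2.44 ± 0.51. IME2 (1.51 ± 0.67) and HSP12 (0.0678 ± 0.69) did not pass. Of 15 stress and reserve carbohydrate genes 10 were higher (13 adjusted over the list alone; 14 positive, adjusted p = 1.56e-09), and of 7 glycolysis genes 5 (6 adjusted over the list alone; 6 positive, adjusted p = 5.73e-06). Ribosomal protein genes had a median of -1.27 and none was called, alone or over all genes (3 of 72 positive, adjusted p = 6.41e-09, but adjusted p = 0.226 with an estimated correlation). In all 104 genes were higher and 52 lower. With size factors 91 were higher and 70 lower, so the share of higher calls moved from 66.7% to 56.5%. The total of 156 was 87 without S. cerevisiae replicate 3 and 101 and 102 without S. paradoxus replicates 1 and 2.

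Among the largest differences between the species were genes with no count in any library of 1 parent. There were 12 such genes in S. cerevisiae and 11 in S. paradoxus, with a mean count of at least 50 in the other parent. They account for 21 of the calls at T0, 18 at M1, 18 at M1M2 and 19 at M2. KEX1 (YGL203C), a protease, was at least 808-fold higher in S. paradoxus at T0, and NUP192 (YJL039C), a nuclear pore protein, at least 587-fold. TIF4631 (YGR162W), a translation initiation factor, was at least 6290-fold lower and SDH9 (YJL045W), a paralogue of succinate dehydrogenase, at least 2990-fold lower. KEX1 stayed at least 590-fold, 450-fold and 357-fold higher at M1, M1M2 and M2, and SDH9 at least 1290-fold, 1300-fold and 1210-fold lower. NUP192 and the nuclear pore gene NSP1 (YJL041W), at 0 in the other parent, are essential in S. cerevisiae, so a count of 0 here does not measure absence of the transcript. Several of these genes are neighbours, such as those from NUP192 to SDH9 on chromosome X. The only 4 open reading frame names that end in C, MCM6 (YGL201C), KEX1, NUP192 and GYP6 (YJL044C), are all among them, at 0 in S. cerevisiae. Genes beside them with names ending in W, ARO8 (YGL202W), NSP1, MHP1 (YJL042W), YJL043W and SDH9, were at 0 in S. paradoxus. The zeros there thus go with the strand of the name. The cause was not tested, and these folds are not read as differences in expression.

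At M1 the species differed in the list of respiratory genes and in single genes of other kinds. HOP1 was higher in S. paradoxus by 3.28 ± 0.8, though its adjusted p was 0.0714 without S. cerevisiae replicate 1 and 0.14 without S. paradoxus replicate 3. MEP2 was higher by 6.24 ± 1.1, while MDH1 was lower at -2.92 ± 0.62 and RPL13A at -5.13 ± 1.1. IME2 was at 1.91 ± 0.67 (adjusted p = 0.118, but 0.00283 without S. cerevisiae replicate 2 and 0.0238 without S. paradoxus replicate 1), and HSP12 at -1.07 ± 0.7. Of 22 early genes 4 were higher (9 adjusted over the list alone; 21 positive, adjusted p = 1.73e-06, but adjusted p = 0.143 with an estimated correlation). Without the shallow libraries 9 of them were called (adjusted p = 3.12e-12), and the middle meiosis list went from adjusted p = 0.464 to 0.000248. Of 16 respiratory genes 1 was lower (7 adjusted over the list alone; 2 positive, adjusted p = 1.92e-05). The total of 88 genes (39 higher, 49 lower) was 54 without S. cerevisiae replicate 2 and 43 and 56 without S. paradoxus replicates 2 and 3.

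At M1M2 most called genes were lower in S. paradoxus. TEF4 (YKL081W), an elongation factor, was at -5.65 ± 0.97. The respiratory genes COX5A (YNL052W) and QCR2 (YPR191W) were at -4.01 ± 0.8 and -2.82 ± 0.61 and GPH1 at -3.12 ± 0.67, but without S. cerevisiae replicate 2, the library with the fewest counts, their adjusted p was 0.324, 0.125 and 0.0919. NDT80 was at 1.59 ± 0.69 and did not pass, but was at 3.73 (adjusted p = 5e-04) without that library. HSP12 was at 0.418 ± 0.69 and did not pass. Of 16 respiratory genes 3 were lower (5 adjusted over the list alone; 2 positive, adjusted p = 9.46e-06), and of 22 middle meiosis genes 1 was higher (1 adjusted over the list alone; 20 positive, adjusted p = 0.000816, but adjusted p = 0.308 with an estimated correlation). Without the shallow libraries 10 of the middle genes were called (adjusted p = 7.12e-15). The total of 105 genes (21 higher, 84 lower) was 55 without S. cerevisiae replicate 2 and 36, 64 and 37 without S. paradoxus replicates 1, 2 and 3. At M2, 37 genes were higher and 29 lower, YJL043W at least 1180-fold lower among them. HSP12 (1.68 ± 0.71) and NDT80 (0.709 ± 0.64) did not pass at M2, and no list passed. The total of 66 was 20 and 32 without S. cerevisiae replicates 2 and 3 and 42 without S. paradoxus replicate 3.

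The change from T0 itself differed between the species, as tested by the interaction. Gene lists were not tested for it, and the genes named were picked for their values. From T0 to M1 TSL1 differed by -5.61 ± 1.1, TPS2 (YDR074W), of trehalose synthesis, by -5.33 ± 1.1, PGK1 by -5.46 ± 0.94, TDH1 by -7.39 ± 1.4, MDH1 by -4.52 ± 0.86 and ALD6 by -5.62 ± 1.2. MEP2 differed the other way, by 6.73 ± 1.3. To M1M2 the differences were -6.24 ± 0.95 for GPH1, -5.89 ± 0.97 for ENO1, -5.77 ± 0.95 for PGK1 and -6.16 ± 1.1 for GSY2. To M2 SSA4 differed by -6.81 ± 1.2 and GPH1 by -4.48 ± 0.91, while MNN1 (YER001W), a mannosyltransferase, differed by 6.95 ± 1.5 and CBF5 (YLR175W), of ribosome biogenesis, by 5 ± 1.1. None of IME2, NDT80, CLB1, CLB3, DIT1 and HSP12 passed at any of these stages. The totals were 61 to M1 (13 up, 48 down), 81 to M1M2 (6 up, 75 down) and 47 to M2 (15 up, 32 down). To M1 the total was 33 without S. cerevisiae T0 replicate 3, 34 without S. paradoxus T0 replicate 2 and 40 without S. paradoxus M1 replicate 2. To M1M2 it was 53, 49 and 33 without S. cerevisiae T0 replicates 1, 2 and 3, and 33 and 40 without S. paradoxus M1M2 replicates 1 and 3. To M2 it was 14 without S. cerevisiae T0 replicate 1, 14 without replicate 3, 22 and 30 without S. cerevisiae M2 replicates 2 and 3, 14 and 19 without S. paradoxus T0 replicates 1 and 2, and 26 and 21 without S. paradoxus M2 replicates 2 and 3.

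At T0 the hybrid was below both parents for genes of several kinds. LEM3 (YNL323W, a membrane protein of lipid transport), EGT2 (YNL327W, a cell wall enzyme) and VNX1 (YNL321W, a vacuolar exchanger) were at -7.07 ± 1.3, -6.02 ± 1.2 and -5.62 ± 0.93 against the parental mean. They lie near each other at the left end of chromosome XIV, and all 3 were more than 2-fold below the parental mean at each stage. The histone genes HHF2 (YNL030W) and HTA1 (YDR225W) were at -4.28 ± 0.87 and -2.55 ± 0.58, RPL31A (YDL075W) at -4.01 ± 0.88 and RPS2 (YGL123W) at -3.47 ± 0.69. MLS1 was above the parental mean by 2.46 ± 0.45. IME2 (1.24 ± 0.51) and NDT80 (1.35 ± 0.51) did not pass. Of 72 ribosomal protein genes 4 were lower (6 adjusted over the list alone; 13 positive, adjusted p = 4.75e-09, but adjusted p = 0.246 with an estimated correlation), and of 7 glycolysis genes 1 (3 adjusted over the list alone; none positive, adjusted p = 0.000872). The meiotic lists lay above the mean, with 17 of 22 middle genes positive and 1 called (6 adjusted over the list alone; median 1, adjusted p = 0.000872), 6 of 7 spore wall genes positive and none called (4 adjusted over the list alone; median 1.47, adjusted p = 0.00519) and 16 of 22 early genes positive and none called (1 adjusted over the list alone; adjusted p = 0.00707). With an estimated correlation none of the 3 passed (adjusted p = 0.318, 0.246 and 0.318). Against the parental mean 19 genes were higher and 13 lower, 27 in all without hybrid replicate 1. In edgeR 7 genes were below both parents and none above, with 33 and 20 at an unadjusted p under 0.05. DESeq2 put 1 gene above both and limma none. The 7 were 4 without hybrid replicate 4 and 4 without S. paradoxus replicate 2.

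**Figure D1:**
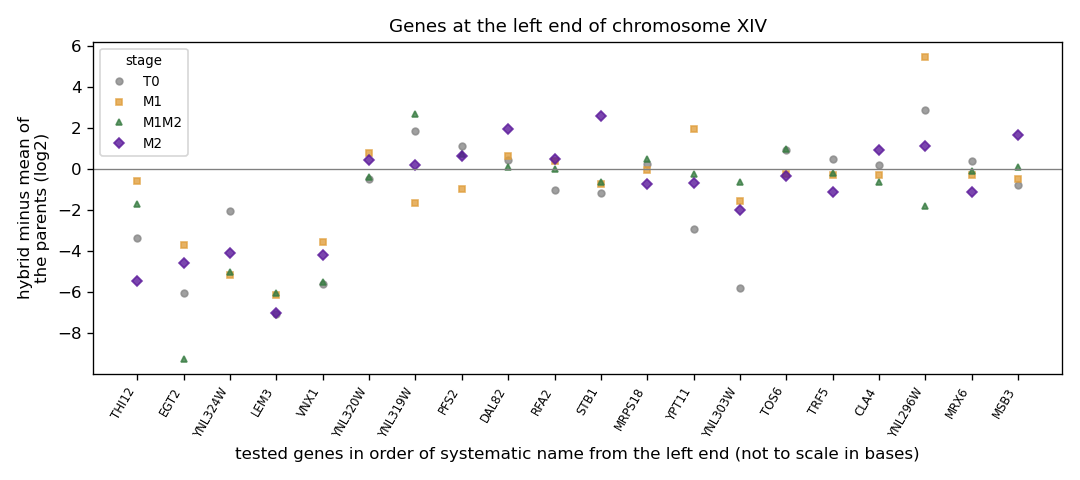
Difference of the hybrid from the mean of the parents (log2) for the first 20 tested genes of the left arm of chromosome XIV, in order of systematic name and not to scale, at each stage (hybrid n = 4, each parent n = 3). EGT2, LEM3 and VNX1 lie far below 0 at all 4 stages, and the next gene, YNL320W, had a mean of 0.0791 over the stages.

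At M1 the hybrid was below both parents for 35 genes, of which 24 encode ribosomal proteins. RPL2B was at -7.2 ± 1 against S. cerevisiae and -6.66 ± 1 against S. paradoxus, and TEF1 (YPR080W), an elongation factor, at -5.3 ± 0.86 and -5.83 ± 0.88. Against the parental mean DMO1 (YJR120W), whose role is not well known, was at -8.49 ± 1.3, KRS1 (YDR037W), a lysine tRNA ligase, at -6.62 ± 1.3, RPS24A (YER074W) at -6.08 ± 1.1, RPL27A (YHR010W) at -5.65 ± 0.96 and ENO2 at -3.99 ± 0.79. MEP2 was above the parental mean by 3.92 ± 0.69 and the arginase CAR1 (YPL111W) by 1.91 ± 0.47. IME2 (0.256 ± 0.51) and NDT80 (-0.415 ± 0.52) did not pass. The same 35 genes were under 0 at T0 as well, with a median of -1.57, against -4.31 at M1, -3.31 at M1M2 and -2.25 at M2. In the deposited table a hybrid value is the sum of the reads given to 1 of the 2 species, so a read that fits both counts nowhere. Of the 35, 29 were more than 2-fold below the parental mean at each of the other three stages, as were 64 genes of all 3094, and 54 genes were so at all 4 stages. Of 72 ribosomal protein genes 37 were below the parental mean (51 adjusted over the list alone; median -2.44, 2 positive, adjusted p = 5.11e-61), and of 7 glycolysis genes 3 (5 adjusted over the list alone; 1 positive, adjusted p = 5.35e-06). Of 22 early meiosis genes 16 were positive and none was called, alone or over all genes (adjusted p = 0.00241, but adjusted p = 0.38 with an estimated correlation). Against the parental mean 22 genes were higher and 57 lower, 52 in all without hybrid replicate 1. None was above both parents in edgeR, DESeq2 or limma, with 13 at an unadjusted p under 0.05 in edgeR. The count above was 1 without S. paradoxus replicate 2, and that below 23, 23 and 16 without hybrid replicates 1 and 4 and S. paradoxus replicate 1. The comparisons with the 2 parents share the hybrid libraries, and with different hybrid replicates for each parent 10 or 8 genes were below both. Lists drawn independently would share 1.47 genes, which leaves out the shared libraries. In 20 simulations without any difference, also between the parents, there were none.

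At M1M2 most middle meiosis and spore wall genes were higher in the hybrid than in the parents' mean. SMK1, OSW1 (YOR255W, spore wall), SPO19 and PES4 were higher by 3.2 ± 0.75, 3.14 ± 0.7, 2.9 ± 0.63 and 2.75 ± 0.58, and CDA1 by 3.15 ± 0.59. CDC20 (YGL116W) and CDC26 (YFR036W), of the complex that drives anaphase, were higher by 3.22 ± 0.6 and 3.33 ± 0.67. NDT80 was higher by 1.75 ± 0.51 (adjusted p = 0.0316) and CLB1 by 2.29 ± 0.69 (adjusted p = 0.0404). The adjusted p of NDT80 was 0.106 without hybrid replicate 1, 0.0982 and 0.0579 without S. cerevisiae replicates 1 and 3 and 0.06 without S. paradoxus replicate 2. That of CLB1 was 0.19, 0.149 and 0.114 without the first 3 of these libraries, and 0.0754 and 0.0962 without S. paradoxus replicates 1 and 2. With size factors the adjusted p of NDT80 was 0.0764 and that of CLB1 0.0615. Against S. cerevisiae alone NDT80 was at 2.55 ± 0.69 (adjusted p = 0.0998 without S. cerevisiae replicate 1) and CLB1 at 3.03 ± 0.97 (adjusted p = 0.112 without hybrid replicate 1, and 0.269 and 0.194 without S. cerevisiae replicates 1 and 3). Against S. paradoxus NDT80 was at 0.959 ± 0.61 and CLB1 at 1.55 ± 0.8, and neither passed. IME2 (0.371 ± 0.51), CLB3 (1.06 ± 0.5), DIT1 (0.0544 ± 0.93) and HSP12 (-1.04 ± 0.56) did not pass against the mean. ENO2 was lower at -5.46 ± 0.86, PGK1 at -4.49 ± 0.61, ENO1 at -4.38 ± 0.62 and RPL2B at -5.94 ± 0.95. Of 22 middle genes 15 were higher (20 adjusted over the list alone; 22 positive, median 2.32, adjusted p = 2.52e-20), and of 7 spore wall genes 5 (5 adjusted over the list alone; 7 positive, adjusted p = 3.09e-07). Against S. paradoxus alone no middle gene was called, yet all 22 were positive (median 1.61, adjusted p = 6.32e-16). In change from T0 no member of either list was called (3 middle and 0 spore wall genes adjusted over the list alone). There the medians were 1.41 and 1.05, with 20 of 22 and 6 of 7 positive (adjusted p = 1.84e-07 and 0.0154, but adjusted p = 0.193 and 0.196 with an estimated correlation). No early gene was called against the mean. Of 72 ribosomal protein genes 18 were lower (29 adjusted over the list alone; 8 positive, adjusted p = 7.76e-29), and of 7 glycolysis genes 5 (5, with 1 higher, adjusted over the list alone; 1 positive, adjusted p = 6.9e-11). Against the mean 76 genes were higher and 67 lower, 91 in all without hybrid replicate 1. In edgeR 15 were below both parents and none above, with 53 and 50 at an unadjusted p under 0.05. DESeq2 put 2 genes above both parents, limma 3 and edgeR without S. cerevisiae replicate 2 or S. paradoxus replicate 3 put 1 and 6.

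**Figure D2:**
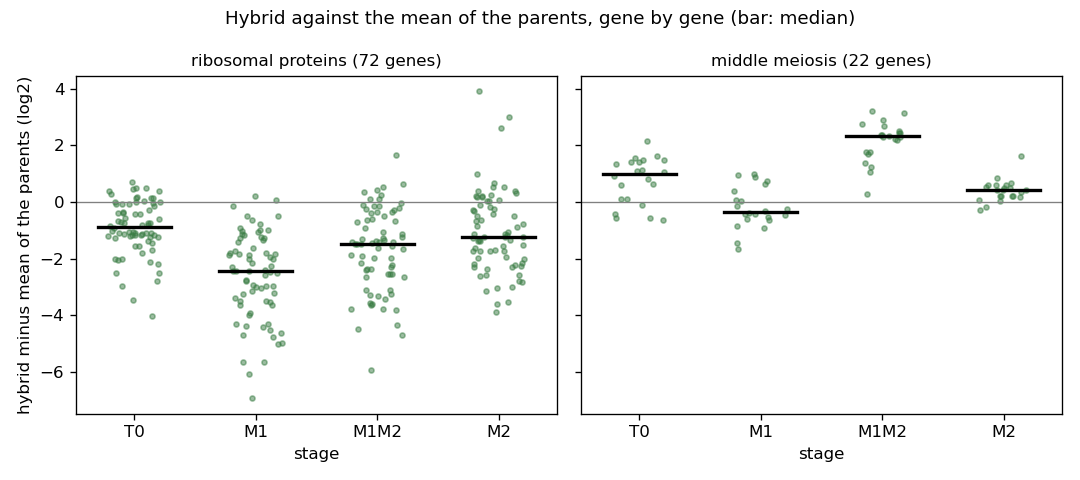
Difference of the hybrid from the mean of the parents (log2) at each stage for the 72 ribosomal protein genes and the 22 middle meiosis genes tested. Points are genes and bars are medians, which reach -2.44 for ribosomal proteins at M1 and 2.32 for middle meiosis at M1M2.

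At M2 the glycolysis list was lower in the hybrid than in the parental mean. ENO1 and ENO2 were lower at -3.27 ± 0.59 and -4.11 ± 0.86, TEF2 (YBR118W) at -4.24 ± 0.75 and KRS1 at -7.65 ± 1.6, and DMO1 was at least 178-fold lower. DIT1 was at 2.67 ± 0.87 and did not pass (adjusted p = 0.133, but 0.0432 without S. cerevisiae replicate 2 and 0.0166 without S. paradoxus replicate 3), and NDT80 was at 0.438 ± 0.5. Of 7 glycolysis genes 3 were lower (4 adjusted over the list alone; 1 positive, adjusted p = 1.24e-05), and of 72 ribosomal protein genes 3 were lower and 1 higher (19 and 3 adjusted over the list alone; median -1.23, 18 positive, adjusted p = 4.31e-12, but adjusted p = 0.254 with an estimated correlation). Against the mean 23 genes were higher and 14 lower, 24 in all without hybrid replicate 3. With size factors 104 were higher and 19 lower, so that the share of higher calls moved from 62.2% to 84.6%. In edgeR 7 genes were below both parents and none above, with 41 and 20 at an unadjusted p under 0.05. DESeq2 put 21 above both and limma 1. The hybrid and the parental mean also differed in their change from T0, a comparison added after the data were seen, for 13 genes to M1M2 (6 up, 7 down), MLS1 among them at -3.47 ± 0.65. That count was 5 without hybrid T0 replicate 1. To M1 and to M2 edgeR called none, with 259 and 210 at an unadjusted p under 0.05, DESeq2 31 and 37 and limma 3 and 0.

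The meiotic lists were also compared by their mean log2 expression in each library. At M1M2 the middle meiosis score was 10.9 ± 0.393 in the hybrid (SD, n = 4), 7.64 ± 1.52 in S. cerevisiae and 9.25 ± 1 in S. paradoxus (SD, n = 3 each). In the exact two-sided permutation tests the hybrid was higher with p = 0.0286 against each parent, the smallest p that 35 splits allow. The spore wall score at M1M2 was 10.1 ± 0.539 in the hybrid against 6.7 ± 0.84 and 8.47 ± 1.15, with exact p = 0.0286 and 0.0571. At M1 the early meiosis score was 7.49 ± 0.257 in the hybrid, 5.5 ± 0.868 in S. cerevisiae (exact p = 0.0286) and 7.67 ± 0.83 in S. paradoxus (exact p = 0.771). At M2 the spore wall score was 12.1 ± 0.193 in the hybrid, 11.4 ± 0.397 in S. cerevisiae and 10.7 ± 0.142 in S. paradoxus. Against each parent the exact permutation test gave p = 0.0286. Of 36 such tests 7 had this smallest p and none passed the correction (exact tests, adjusted p = 0.147). The 20 splits between the parents cannot give an exact p below 0.1.

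**Figure D3:**
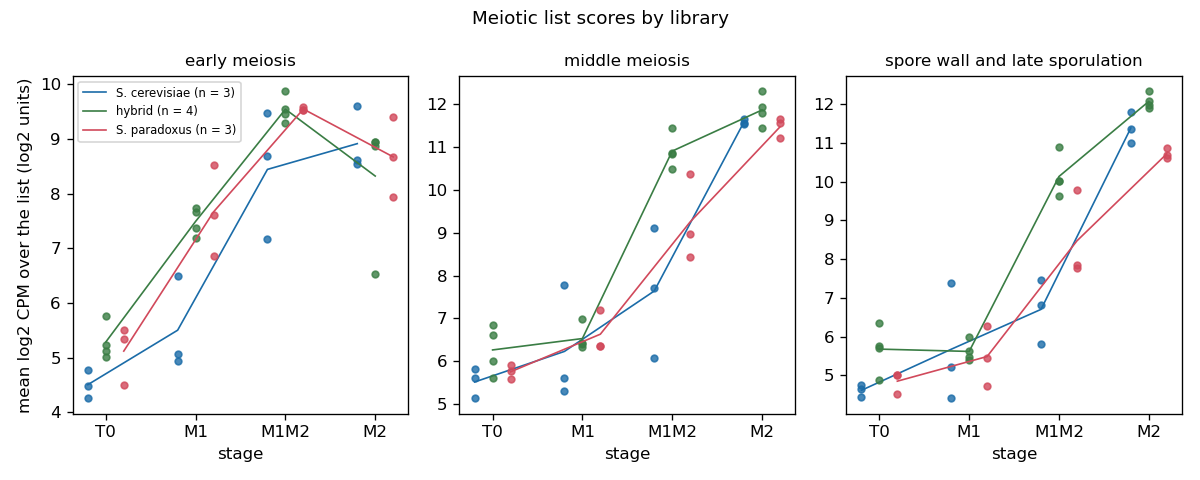
Mean log2 CPM over the genes of 3 meiotic lists in each library (points) by stage, with lines through the group means of S. cerevisiae (n = 3), the hybrid (n = 4) and S. paradoxus (n = 3). At M1M2 the hybrid means for middle meiosis and the spore wall, 10.9 and 10.1, are above those of both parents.

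The direction of misexpression was compared with the direction of the parental time course. Of the genes outside both parents at M1, 31 of 35 (88.6%) deviated in the direction of the parental change from T0 to M1M2, and at M1M2, 14 of 15 (93.3%) in the direction of the change from M1 to M2. As all these genes were below both parents, Fisher's exact test could not differ from p = 1. Against the parental mean, a version added after the data were seen, the shares were 78.5% of 79 genes at M1 and 91.6% of 143 at M1M2 (Fisher's exact p = 0.000357 and 4.43e-26). At M1 the higher genes split evenly, 11 along the course and 11 against it, so that share comes from the lower genes (51 of 57), while at M1M2 71 of 76 higher and 60 of 67 lower genes went along it. Without the 54 genes low at all stages they were 72.1% of 43 and 92% of 113 (Fisher's exact p = 0.00153 and 7.15e-19). The genes include the higher middle meiosis genes and the lower ribosomal protein genes, and genes are not independent. Matched over 300 genes to the stage means of S. cerevisiae, 3 of 4 hybrid M1 libraries and 4 of 4 M1M2 libraries were nearest to a later stage than their own. Matched to S. paradoxus, 0 and 2 were, and so was 1 of its own 3 M1M2 libraries. With all genes in place of the 300, 1 hybrid M1 library was nearest to a later S. cerevisiae stage and 0 M1M2 libraries to a later S. paradoxus stage. All T0 and M2 hybrid libraries matched their own stage on both scales, and all 3 S. paradoxus M1M2 libraries were nearest to a later stage of S. cerevisiae. The S. cerevisiae scale is uncertain, since of its own M1M2 libraries 1 was nearest to an earlier stage, 1 to its own and 1 to a later one, and of its M1 libraries 1 to an earlier stage and 2 to their own.

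Within the hybrid the alleles of the species were compared, in 1 cell and under the same regulators. At M1 GMC2 (YLR445W), of meiotic recombination, had more S. paradoxus transcript by 6.74 ± 1.2, whereas MLS1 was at -1.28 ± 0.25 (adjusted p = 0.122 without replicate 4) and COX26 (YDR119W-A), a respiratory subunit, at -5.35 ± 1.1 (adjusted p = 0.054 without replicate 1). At M1M2 PDH1 (YPR002W), of propionate use, was at -3.05 ± 0.44 and AQY1 (YPR192W), a spore water channel, at -4.36 ± 0.85. At M2 PCK1 (YKR097W), of gluconeogenesis, was at 1.4 ± 0.22, SFC1 (YJR095W), a mitochondrial succinate carrier, at 2.49 ± 0.51, NUM1 (YDR150W), of the cell cortex, at -3.56 ± 0.69 and GMC2 at 5.17 ± 1.1 (adjusted p = 0.0546 without replicate 4). KEX1, a gene at 0 in S. cerevisiae, was at least 458-fold, 1090-fold and 359-fold higher from the S. paradoxus allele at M1, M1M2 and M2. SDH9 was at least 1630-fold, 1450-fold and 1460-fold lower. NDT80 was at 0.787 ± 0.4 at M1M2, and none of IME2, NDT80, CLB1, CLB3, DIT1 and HSP12 passed at any stage. The calls numbered 26 at M1 (14 higher, 12 lower), 25 at M1M2 (13, 12) and 46 at M2 (23, 23). ARO8 (YGL202W), TIF4631, GTR2 (YGR163W), NUP192, NSP1, MHP1 (YJL042W) and GYP6 (YJL044C) were among the calls at M1 and M1M2. At M1M2 so were RUF5-2, MCM6 (YGL201C), YRF1-2 (YER190W), YHR054W-A, YJL043W and ERR1 (YOR393W). Each had 1 allele at 0 in the hybrid libraries of those stages. Like KEX1 and SDH9, they were at 0 in all libraries of 1 parent, where a 0 does not measure absence of the transcript. The totals, above all the 25 at M1M2, therefore include many genes that need not differ between the alleles. Fits of 1 stage alone gave 57 at M1M2 and 1 at M2. In them GMC2 at M1 (adjusted p = 0.118) and all genes named here at M2 were lost, with adjusted p = 0.0592 for PCK1, 0.352 for SFC1, 0.252 for NUM1, 0.141 for GMC2 and KEX1 and 0.0598 for SDH9. At M1 there were 10, 12 and 16 without replicates 1, 3 and 4. At M1M2 there were 14, 16, 14 and 14 without replicates 1 to 4 in turn, and at M2 27, 24, 30 and 15. At T0 the 4 calls were RUF5-2 and YHR054W-A, both at 0 in S. cerevisiae, HEF3 (YNL014W), a translation factor named after its value was seen, at -2.54, and DON1 (YDR273W), of the spore membrane, at -1.52 ± 0.33. In T0 replicate 1 the S. paradoxus share of allele counts was 65.49%, where the other T0 libraries had 49.48 to 51.77%, and 14.7% of its features with at least 20 counts equalled those of the S. cerevisiae allele of replicate 2, so the T0 comparison rests on a library that is in question. A fit of T0 alone called none of these 4 (adjusted p = 1 for each). Without replicate 1 there were 20 calls, and without replicate 2, 3 or 4 none, where the adjusted p of DON1 was 0.056, 0.642 and 0.338.

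The parental difference was set against the allele difference, which tests the part that the alleles do not keep in 1 cell. The 2 alleles of a hybrid library entered this fit as separate columns, so its SEs and calls leave their pairing out. At T0 PGK1 differed by 4.51 ± 1 and MLS1 by -3.71 ± 0.71 more between the parents than between the alleles. These are 2 of 25 such genes (14 up, 11 down), and there were 7 without hybrid replicate 1 and 16 without S. paradoxus replicate 2. At M1 the 3 genes were MEP2 (6.07 ± 1.3), CAR1 (4.18 ± 0.97) and the cell wall gene CWP1 (YKL096W, -3.45 ± 0.75). None of the 3 was called without hybrid replicate 1 or 3 or 4, S. cerevisiae replicate 2 or S. paradoxus replicate 2. MEP2 was also lost without S. cerevisiae replicates 1 and 3, CWP1 without S. paradoxus replicate 3 and in a fit of 1 stage alone (adjusted p = 0.0602) and CAR1 without any single library. The count was 0 to 6 over these fits. At M1M2 and M2 edgeR called none, with 169 and 113 at an unadjusted p under 0.05, and DESeq2 17 and 7. The M1M2 count was 1 without S. cerevisiae replicate 2.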

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

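The comparison of the hybrid with the parental mean in change from T0, the search for equal counts between allele columns and the count of genes at 0 in 1 parent were chosen only after the results were seen. In the hybrid, with 4 libraries per stage, 24 groups of values were searched for a library far from the other 3, and 4 stood out, where chance gives about 1 in 20 groups.

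Hybrid T0 replicate 1 had 65.49% of its allele counts from S. paradoxus (Wilson interval 65.44 to 65.55), while the other three libraries had 49.48 to 51.77%. The first explanation weighed is that values of another library are in this column. Of its features with at least 20 counts, 14.7% (418 of 2846) equalled those of the S. cerevisiae allele column of replicate 2, and the next highest of 1524 pairs of columns had 0.5785%. At the 23 genes with no count in 1 parent, replicate 1 had counts for that parent's allele at 18, and each of the other 15 hybrid libraries at no more than 1, which is consistent with counts of the other allele in both allele columns of this library, not in the S. paradoxus column alone. A real excess of S. paradoxus transcripts is argued against, since the allele ratio correlated across genes with that of replicates 3 and 4 with rho -0.0548, against 0.236 for replicate 2 (2661 genes, which are not independent). How the values came to be shared was not tested, and no biological explanation other than a real excess was tested.

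In hybrid M2 replicate 4 the S. paradoxus share was 50.63%, against 51.76 to 51.81% in the other three. The middle meiosis score of hybrid M1 replicate 4 was 6.989, above 6.323 to 6.414 in the others. The early meiosis score of hybrid M2 replicate 3 was 6.53, below 8.865 to 8.951, and this library had only 117049 counts in genes. No explanation was tested for these.

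The change from T0 differed between the species for 61 genes at M1, 81 at M1M2 and 47 at M2, by a test of the difference itself. Fitted on the groups compared alone, the real split of the libraries gave 65 genes at M1, and 2 of 100 splits gave as many, with 92 the highest of the others. At M1M2 it gave 58, reached by 2 of 100, with 786 the highest, and at M2 38, reached by 4 of 100, with 252 the highest. The splits shuffled stage labels within each species, so they bear on any stage change and not on a difference between the species. A split that swaps the stages in either species alone turns the shared change into a difference, which can give counts above the real one. The splits therefore cannot decide whether the difference in change arose by chance. The hybrid changed differently from the parental mean for 13 genes at M1M2.

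Features that name no gene, which the comparisons do not use, took more of the counts after T0, with a mean over libraries of 2.12% at M1, 2.49% at M1M2 and 2.78% at M2, against 0.903% at T0. Part of this lay at the replication origin ARS1507, at 7.37 CPM at T0 and 4150 at M2 in S. cerevisiae, 4.56 and 2330 in S. paradoxus and 15.2 and 2420 in the hybrid. Whether these counts come from transcripts of neighbouring genes was not tested.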

How the results depend on the processing

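Depth limits the results, as 4 libraries had few counts and small changes could not be detected. The fits without these 4 shallow libraries, without hybrid T0 replicate 1, without genes low at all stages, of alleles at 1 stage only and of directions against the parental mean were chosen only after the data were seen. Of the counts, scores and list results under settings other than leaving out 1 library, 231 kept their side of the threshold or stayed within 1.5 times. Another 5 newly passed and 87 moved further. Only the shares of genes along the parental course could newly pass or reverse, and none of these reversed. For each value below the cause was not tested, except where fewer libraries or genes were used.

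The DESeq2 Wald test called 526 and 616 genes in S. cerevisiae at M1 and M1M2, 210 in S. paradoxus at M1 and 600 in the hybrid at M1. It called 370, 235, 196 and 194 between the species from T0 to M2, 192, 138 and 141 in species change, 73, 124 and 236 for the hybrid against the parental mean at T0, M1 and M2, 1, 2 and 21 above both parents at T0, M1M2 and M2, 14, 26 and 13 below them, 80, 212, 107 and 196 between alleles, and 73, 13, 17 and 7 for parental against allele differences. Limma on the deposited values called 452 in S. cerevisiae at M1, 332, 66 and 147 between the species at T0, M1M2 and M2, 72 in species change to M2, 11 and 8 below both parents at T0 and M1M2, 3 and 1 above them at M1M2 and M2, and 16, 16 and 138 between alleles from M1 to M2.

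With only the groups compared there were 68 and 610 in S. paradoxus at M1 and M1M2, 380, 36 and 32 between the species at T0, M1 and M1M2, 14 and 3 below both parents at T0 and M2, and 4 above them at M2. Without the shallow libraries there were 181 in S. paradoxus at M1, 311 between the species at T0, 107, 129 and 84 in species change, 23 for the hybrid against the mean at M2, 1 and 3 above both parents at T0 and M1M2, 30 between alleles at M2, and 57, 5 and 12 for parental against allele differences at T0, M1 and M1M2. HSP12 in S. cerevisiae at M1 reversed from 0.339 to -2.86 without the shallow libraries and to -2.79 without M1 replicate 2 alone, with values from -2.79 to 0.871 on leaving out 1 library in turn. DESeq2 size factors gave 123 (104 higher, 19 lower) for the hybrid against the mean at M2 and 1 for parental against allele differences at M1. A replicate block gave 22 for the hybrid against the mean at M2 and moved no other count by over 1.5 times, though the numbers do not pair the libraries. Across genes, 7 of 60 pairs with the same number within a genotype had a correlation above 0.1, and 3 of 36 across genotypes.

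Without the genes low at all stages 1, 6, 0 and 0 were below both parents from T0 to M2, a drop largely fixed in advance, since the stage counted also decides which genes are left out. With different hybrid replicates for each parent there were 0 or 1, 10 or 8, 1 or 6 and 0 or 2. With no filter 7 and 45 genes differed between alleles at T0 and M1, with no library block 1 at T0, and with stage-only fits 0, 57 and 1 at T0, M1M2 and M2. Without hybrid T0 replicate 1 there were 20 at T0. With an estimated correlation 47 of 86 list calls between stages, 5 of 21 between species and 10 of 27 for the hybrid passed. The share of genes that deviated along the parental course passed Fisher's exact test at M1 and M1M2 for genes called against the parental mean (78.5 and 91.6%), also without low genes (72.1 and 92%) and without low genes and shallow libraries (78.6 and 95.5%), and at M1M2 for genes outside both parents without shallow libraries (89.5%; 90.5% at M1 with p = 1). With all genes 1 hybrid M1 library matched a later S. cerevisiae stage and 0 of the M1M2 libraries a later S. paradoxus stage, and with Pearson's correlation 4 did.

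Leaving out 1 library in turn gave 134 to 267 and 225 to 306 genes in S. cerevisiae at M1 and M1M2, 66 to 101, 163 to 227 and 306 to 451 in S. paradoxus at M1, M1M2 and M2, and 246 to 330 in the hybrid at M1. Between the species it gave 87 to 129, 43 to 82, 36 to 129 and 20 to 54 from T0 to M2, and in species change 33 to 75, 33 to 87 and 14 to 42. Against the parental mean it gave 52 to 89, 91 to 147 and 24 to 37 from M1 to M2. Below both parents were 4 to 8 at T0 and 16 to 41 at M1, and above them 0 to 1 at M1 and 0 to 6 at M1M2. Between alleles there were 0 to 20, 10 to 25, 14 to 16 and 15 to 30 from T0 to M2, and for parental against allele differences 7 to 31, 0 to 6 and 0 to 1 from T0 to M1M2. The share of genes outside both parents along the parental course at M1M2 was 82.4 to 95.2%, and passed Fisher's exact test only without S. paradoxus M1M2 replicate 3. Of 274 named genes in their comparisons 30 had a call changed by leaving out 1 library. Calls of named genes were lost for 17 with only the groups compared, 12 of 25 with fits of 1 stage alone, 9 with limma, 5 with size factors, 5 with no library block, 4 with a replicate block, 4 without shallow libraries, 2 with a common scaling of both alleles and 1 with no filter.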

Other observations

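The tests of the shallow libraries, of count loss at every stage, of a rise of all genes and of libraries further along the parental course were chosen only after the results were seen. The hybrid went through the programme of both parents, with 10 of 22 early meiosis genes up at M1 (adjusted p = 0.0666 for the list with an estimated correlation), NDT80 and most middle genes up by M1M2 and all 7 spore wall genes up at M2, while most ribosomal protein genes fell. Its differences from the parental mean included lower ribosomal protein genes at M1 and M1M2, lower glycolysis genes at all 4 stages and higher middle meiosis and spore wall genes at M1M2. Lower glycolysis genes were not weighed here. ENO1, ENO2 and PGK1, the glycolysis genes called below both parents, were more than 2-fold below the parental mean at all 4 stages. Counts lost where a read fits both species could lower them too, so they need not be a trait of the hybrid.

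The 35 genes below both parents at M1, 24 of them for ribosomal proteins, may reflect counts that are lost in the hybrid at every stage where a read fits both species. They had a median of -1.57 against the parental mean at T0 too, but such a loss would be the same at every stage, and theirs was -4.31 at M1, where they were picked, -3.31 at M1M2 and -2.25 at M2. Shallow libraries as the cause are argued against, since 42 genes were below both parents without the 4 shallow ones. A faster loss of these transcripts in the hybrid may add to it, since ribosomal protein genes within 0.5 of the parental mean at T0 had a median of -1.22 at M1. Genes picked for a value near 0 at T0 can drift from it by chance, and the difference in change of the list had a median of -1.52 (5 of 72 positive, adjusted p = 1.26e-19, but adjusted p = 0.107 with an estimated correlation), so both explanations stay open.

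Middle meiosis and spore wall genes above the parental mean at M1M2 are consistent with hybrid libraries further along the parental course, since 89% of the 82 called genes that are in none of the gene lists and not low at all stages deviated in the direction of the parental change from M1 to M2. Shallow libraries are argued against, as 18 of 22 middle genes were called without them. A late S. cerevisiae group alone is argued against less firmly. The middle list passed camera against S. paradoxus too (adjusted p = 6.32e-16, and 0.0241 with an estimated correlation). No single middle gene was called there, and the exact permutation test of the score gave p = 0.0286 (adjusted p = 0.147). A rise of all genes alike is argued against, since the median of the members was 2.29 above that of the other genes, which scaling does not change. The middle list was also above the mean at T0 (median 1, adjusted p = 0.000872, but adjusted p = 0.318 with an estimated correlation). A meiosis that runs ahead in the hybrid and cultures sampled at different points cannot be told apart, because the score ranged over 1.94 among the S. paradoxus M1M2 libraries alone and no measure of cell stage was used here.

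LEM3, EGT2 and VNX1, with means over the stages of -6.58, -5.89 and -4.73 against the parental mean, are neighbours near the left end of chromosome XIV. A candidate explanation is a segment whose sequence the parental strains share, in which no hybrid read can be given to 1 species, as European S. paradoxus carries such a segment from S. cerevisiae. The planned test, a median of 0.0791 over the 5 neighbouring genes, went against it, but 3 of these lie past VNX1, the first of them YNL320W, so it argues only against a segment that reaches beyond VNX1. The other two, YNL324W (-4.08) and THI12 (-2.77, but -0.571 at M1), had mean counts of 13.9 and 14.6, too few to decide. YNL319W, a tested gene that follows YNL320W in name order, was left out of the median. It was at 1.87, -1.66, 2.66 and 0.21 against the parental mean from T0 to M2. The sequence of S. paradoxus was not used here, so a shorter segment stays open.

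Other splits of the libraries, fitted on the groups compared alone, gave these counts. For the hybrid against T0 the real splits gave 442, 803 and 613 genes at M1, M1M2 and M2 with a highest other of 0 among 35. This argues against chance but cannot exclude it, since 35 splits allow no very small share. Hybrid T0 replicate 1, whose values are partly shared with replicate 2, is also in each of these splits. For S. cerevisiae (295, 384 and 753), S. paradoxus (68, 610 and 525) and the species at the 4 stages (380, 36, 32 and 69) the highest other was 0, and 10 splits are too few for a share under 0.05. Outside both parents lay 14, 34, 13 and 7 genes from T0 to M2, with 4, 25, 8 and 2 the highest of the others, and against the parental mean 38, 61, 145 and 26, with 23, 52, 40 and 8. Only 1 of 100 splits, the real one, gave as many in each of these 8 comparisons. These splits mixed the libraries of all 3 genotypes, and the parents also differ from each other. They argue against 3 genotypes that are alike, but cannot exclude chance for the deviation of the hybrid itself. For the alleles (0, 24, 57 and 1) the highest other was 0, all 8 splits gave as many at T0 and 1 of 8 at the later stages, and 8 splits are too few. For parental against allele differences the real split gave 33 genes at T0, with 11 the highest other. It gave 3 at M1 (reached by 5 of 100, highest other 34), 0 at M1M2 (reached by 100, highest other 84) and 0 at M2 (reached by 100, highest other 15). These splits exchanged parental libraries with hybrid allele columns of the same species. An exchange in either species alone brings the difference between hybrid and parents into the contrast, which can give counts above the real one. The splits therefore cannot exclude chance at any stage. In the fit of all stages the T0 count of 25 was 7 without hybrid T0 replicate 1, whose allele counts are in question.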
